A study of Mus musculus with 12 samples.

How the data were processed

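RNA of 12 samples of mouse embryonic fibroblasts (MEFs) was labelled with Cy3 and hybridised to 12 one-colour Agilent arrays. The arrays carried 45018 spots, of which 1639 were control spots and 43379 held 41174 distinct probes. Each group held 3 arrays: WT vehicle, WT Dex, GR-C3 vehicle and GR-C3 Dex. Groups and replicate numbers were taken from the labels. The labels call the samples of a group biological replicates and do not say whether they came from separate embryos or cultures, so all p-values measure the spread between these samples only.

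The deposited scanner files hold spot intensity values on a linear scale. Per the file headers they were made with Agilent Feature Extraction 9.5.3.1, with spatial and multiplicative detrending and with surrogate values for low signals. The submitters' processing notes name Feature Extraction 9.5. The processed signal used here is the authors' background-subtracted intensity of each spot, not yet scaled between arrays. The deposited series matrix held intensity values equal to the processed signal for all 45018 spots within a tolerance of 1e-09, with column medians of 77.9 to 154. Its scale was therefore linear and uncentred and was known in full. Probe positions were given per the file headers in mouse build mm7, and no genome or exon annotation of that build was used here.

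The log2 processed signal minus the 75th percentile of its array was the expression value. That percentile lay between 884 and 1821 on the 12 arrays, and 71.3 to 79.1% of probes were well above background by the scanner's own call. The median coefficient of variation of replicated probes was 3.77 to 7.67%. Control spots and spots with an outlier call were left out, saturated spots were kept, and spots of 1 probe were averaged. A probe was kept if it was well above background on all arrays of at least 1 group, which kept 30935 probes and left out 10239. Accessions named 23075 probes, symbols 6582 and synonyms 3077 through a RefSeq gene table, and 8440 kept the name in the file. Of the probes of a gene the one with the highest mean was used, which gave 20834 genes. Of these, 7076 had several kept probes and 125 had a missing value on some array.

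Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit with 1 coefficient per group over all 12 arrays, then eBayes), and Benjamini-Hochberg adjusted p-values under 0.05 were called. The comparisons were Dex against vehicle in each genotype, GR-C3 against WT under each treatment, and the interaction, which is the GR-C3 Dex change minus the WT Dex change. Each log2 change is given with its standard error, written ±, and group levels are given with their SD. A probe that was well above background on none of the arrays of a group has only a bound there. Its change is then given as "at least N-fold": the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Where some arrays of a group measured a probe, their number is given beside the fitted change, which then includes signals near background. No fold is given where the bound falls under 1 or where neither group was well above background. Outliers within groups were not tested, since the groups hold 3 arrays. Permutation of 3 arrays against 3 cannot give a p-value below 0.1.

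Of 35 gene lists (responses, pathways and cell type markers), 34 were tested as sets with camera at a preset correlation between genes of 0.01, with an estimated correlation, and with fry. The adjusted p of a list is over these 34. Fry tests whether the genes of a list move, on balance, in 1 direction and does not compare the list with other genes. With an estimated correlation on all 12 arrays, the Hox list under vehicle was the 1 call that held among the 4 comparisons Dex in WT, Dex in GR-C3, interaction and genotype under vehicle. The size of the Dex response was compared over genes with a called average Dex effect over both genotypes, with camera on their interaction values. Camera used the preset correlation of 0.01 there, and an estimated correlation was not tried. The genotypes were weighted to make this average uncorrelated with the interaction, which gave WT a weight of 0.5 with 12 arrays and 0.444 with 11. With equal weights 3151 genes were called with 11 arrays.

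Named genes were chosen by a rule. It took Nr3c1, and the 8 largest and 8 smallest log2 changes among called genes of each comparison whose groups did not overlap, with 3 and 3 for genotype under Dex and no demand on overlap for the interaction. It also took up to 4 called members with the smallest p of each list described, up to 2 members with the highest signal where none was called, and 5 sex-linked genes. Names that were accessions, probe numbers, RIKEN or LOC names or predicted genes were passed over, and some genes that the rule took are not reported here. The grouping, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were quantile normalization, normexp background correction (offset 50), no filter on dim probes, the mean of a gene's probes, slide as a fixed or random block, a replicate block, trend and robust options, array weights, fits of only the groups compared, other thresholds and leaving out each array. The array labelled WT vehicle replicate 1 stood apart. List tests and genes named from the fit without it, its removal together with other settings, and the choice to give values without it beside the others came after seeing the data. The same holds for normexp with repaired local backgrounds and for counts and response size within slides. Within slides a group with 1 array is assumed to vary like the other groups.

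The tests were tried on simulated data. For WT Dex against WT vehicle with 12 arrays and 20709 genes, 36.4% of genes changed by 0.5 on the log2 scale, 77.6% of those changed by 1, 94.8% of those changed by 2 and 100% of those changed by 4 were called, over 5 runs with 50 genes of each size. Of unchanged genes 0.04% were called. For the simulated interaction the shares were 15.6, 59.2, 88.8 and 100%. The simulated values were independent between arrays, with the spread of the fit without the array labelled WT vehicle replicate 1. They held neither an array like that one nor a slide effect, so these shares do not apply to the 12 arrays as measured. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures, and statmod 1.5.0 gave the random blocks.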

Results

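Gene expression was measured in mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos of a C57Bl/6 background. WT cells were compared with cells of the homozygous GR-C3 knockin. Nr3c1 is the gene of the glucocorticoid receptor (GR), and in the knockin its only start codon left is that of the shorter GR-C3 translational isoform. Cells of both genotypes received vehicle or 100 nM dexamethasone (Dex), a synthetic glucocorticoid that activates the GR, for 6 hours. Each of the 4 groups held 3 arrays. The comparisons address which genes Dex changes in each genotype, whether the responses differ, and how the genotypes differ before and after Dex. On the 12 arrays, 71.3 to 79.1% of probes were well above background, and the number of arrays limits the precision. All levels are normalized log2 signals relative to the 75th percentile of the array.

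The array labelled WT vehicle replicate 1 stood apart from its group. Its values correlated across genes, which are not independent replicates, at 0.983 with the other WT vehicle arrays. Those correlated at 0.998 with each other. With the 3 WT Dex arrays it correlated at 0.988 to 0.989, below the 0.992 to 0.995 of these with each other. It was the only array on slide 1 and on scan day 2. Fkbp5, a co-chaperone that lowers hormone binding by the GR (probe at chromosome 17, 26586393 to 26586452, build mm7), lay at 1.51 on this array and at -2.64 and -2.74 on the other WT vehicle arrays. The WT Dex arrays held Fkbp5 at 2.15, 1.90 and 2.06. Lcn2, an iron-siderophore carrier, lay at -0.09 on the array labelled WT vehicle replicate 1, against -5.55 and -4.96 in the other WT vehicle arrays and -0.09, -0.33 and 0.25 in WT Dex. The cytokine gene Il6 lay at -3.45 on this array, against -1.59 on each of the other WT vehicle arrays and -3.46, -3.15 and -3.66 in WT Dex. The 12-array values of the Dex comparisons are therefore followed by those without this array, and genotype differences are from all 12 arrays unless stated. Leaving out each array in turn was planned, and giving this one such room was chosen after seeing the data and from the outcome itself.

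**Figure D1:**
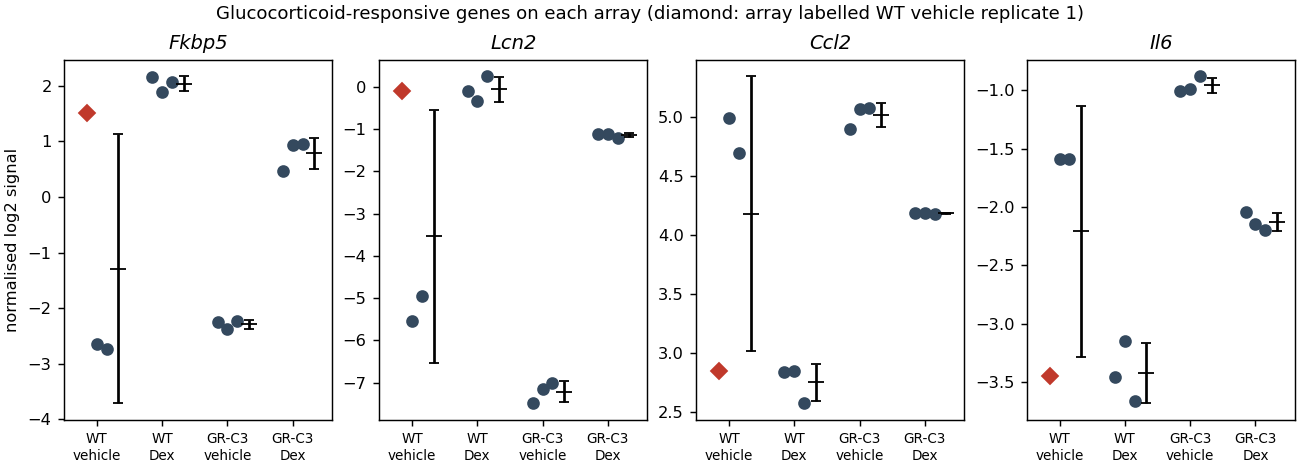
Normalized log2 signal (vertical axis) of Fkbp5, Lcn2, Ccl2 and Il6 on each array of the 4 groups (horizontal axis), with bars for the group mean ± SD (n = 3) and a diamond for the array labelled WT vehicle replicate 1. That array held Fkbp5 at 1.51, close to the WT Dex arrays at 1.90 to 2.15.

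Nr3c1, the edited gene, was measured on every array. Its probe lies at chromosome 18, 39787242 to 39787301 in build mm7. Its level was 1.20, 1.80 and 1.80 on the WT vehicle arrays, of which 1.20 is that of the array labelled WT vehicle replicate 1. In WT Dex it was 1.27, 1.06 and 1.07, in GR-C3 vehicle 1.86, 1.83 and 1.86, and in GR-C3 Dex 1.53, 1.44 and 1.39. The group means were 1.60 ± 0.35, 1.13 ± 0.12, 1.85 ± 0.016 and 1.45 ± 0.069 (SD, n = 3). No difference in Nr3c1 passed the test with 12 arrays. The log2 change with Dex was -0.47 ± 0.15 in WT (adjusted p = 0.189) and -0.40 ± 0.15 in GR-C3 (adjusted p = 0.355), and GR-C3 vehicle lay 0.25 above WT vehicle (adjusted p = 0.259). Without the array labelled WT vehicle replicate 1, Nr3c1 fell with Dex by 0.67 in WT (SE 0.092, adjusted p = 0.0013). By the same probe it then fell in GR-C3 cells by 0.40 (SE 0.082, adjusted p = 0.0299), with an interaction of 0.27 (adjusted p = 0.359). The edit removes start codons, not the transcript, so the Nr3c1 level does not check the genotype labels. The 3 other Nr3c1 probes kept differed from this one, with genotype differences under vehicle of 0.02, -0.25 and -0.36 over all 12 arrays. Without the array labelled WT vehicle replicate 1 these differences were -0.475, -0.501 and -0.575, against 0.05 by the probe above. The Dex changes of the 3 other probes were 0.22, -0.22 and -0.08 in GR-C3 cells. In WT cells, without that array, they were -0.50, -0.75 and -0.64.

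Dex in WT cells, over all 12 arrays, raised Tcim, a modulator of Wnt signalling, from -1.18 ± 0.80 to 0.94 ± 0.17 (SD, n = 3), a log2 change of 2.12 ± 0.30 (adjusted p = 0.0382). Fam89a rose by 1.43 ± 0.20 and the atypical chemokine receptor gene Ackr4 by 1.12 ± 0.12 (adjusted p = 0.0241). The small heat shock protein gene Hspb8 rose by 0.997 ± 0.13 and the selenium carrier gene Selenop by 0.89 ± 0.13. Pde4b, a cAMP phosphodiesterase, changed by -1.16 ± 0.13 (adjusted p = 0.0247), Dkk2, a Wnt modulator, by -1.08 ± 0.14, Prtg by -1.08 ± 0.16 and the tyrosine phosphatase gene Ptpre by -0.995 ± 0.14 (adjusted p of 0.0382 to 0.0415). The chemokine gene Ccl4 was at least 1.68-fold lower, as it was not well above background in WT Dex. The changes in Prtg, Pde4b and Ccl4 turned to 1.44, 0.41 and 2.16 with the planned normexp background correction, with which limma called 0 genes in this comparison (12210 at an unadjusted p under 0.05) and the median change of all genes was 0.55. Local backgrounds with an outlier call reached 65361 under this correction. With these replaced, a setting chosen after seeing the data, Prtg, Pde4b and Ccl4 kept their downward sign. In all, 25 of 20834 genes changed, 8 higher and 17 lower. Of these, 10 changed at least 2-fold, 3 higher and 7 lower, and 4 of the lower were not well above background in WT Dex. With quantile normalization 15 rose and 15 fell, with normexp and quantile normalization 56 and 70, and with normexp on repaired local backgrounds, chosen after seeing the data, 24 and 14. Without each array in turn the count ran from 0 to 92, apart from 2548 without the array labelled WT vehicle replicate 1. That array counted as vehicle in the 25 calls. Genes in which it lay near the WT Dex arrays, such as Fkbp5, could therefore hardly pass. A fit of the WT arrays alone called 0 genes.

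Genes widely described as induced by glucocorticoids rose as a list in WT cells by a median of 1.07 over 35 measured members (camera adjusted p = 1.73e-13, adjusted p = 0.484 with an estimated correlation). None of the members passed the test over all genes with limma, while 20 rose and 1 fell adjusted over the list alone. Of all genes tested, 3473 had an unadjusted p under 0.05. Mt2, a metallothionein, changed by 2.53 ± 0.71 (adjusted p = 0.152) and Fkbp5 by 3.33 (adjusted p = 0.129). The list of cytokines, chemokines and inflammatory enzymes fell by a median of 0.49 (27 members, camera adjusted p = 1.29e-05, adjusted p = 0.484 with an estimated correlation), with 6 members lower adjusted over the list alone. Its member Ccl2, a monocyte chemokine, changed by -1.43 ± 0.42 (adjusted p = 0.165). Smaller shifts were called upward for the lists of extracellular matrix (median 0.18, camera adjusted p = 0.000335), adipocyte (0.20, 0.0184) and hypoxia genes (0.16, 0.0111). The same held for heat shock (0.23, 0.0105), contractile (0.13, 0.0304) and chondrocyte genes (0.27, 0.0184). Downward shifts were called for Hox genes (median -0.13, camera adjusted p = 0.022) and interferon-stimulated genes (-0.15, 0.0432). Each of these smaller calls was lost with an estimated correlation (adjusted p = 0.484 or 0.531 with an estimated correlation). Contractile and interferon-stimulated genes were not called with quantile normalization (adjusted p = 0.196 and 0.0604). Under the planned normexp correction the calls of the glucocorticoid-induced (median 0.87, adjusted p = 0.124), inflammatory (0.368), adipocyte (0.458), chondrocyte (0.69), hypoxia (0.226) and interferon-stimulated lists (0.797) ended. Medians there turned to 0.64 for inflammatory, -0.28 for matrix, -0.05 for hypoxia, -0.29 for heat shock, -0.42 for contractile, 1.44 for Hox and 0.52 for interferon-stimulated genes. Camera then called matrix, contractile and heat shock genes lower (adjusted p = 0.000892, 0.00474 and 0.0144) and Hox genes higher (0.00419), and kept a downward sign for the inflammatory list. With slide as a block the calls of these 8 smaller shifts were kept, with medians of 0.08 for matrix, 0.09 for adipocyte, 0.45 for chondrocyte, -0.25 for Hox and -0.30 for interferon-stimulated genes. Over all genes tested, the 2 members of these 8 lists that passed were Hspb8, and the Hox gene Hoxc6 at -0.72 ± 0.11 (adjusted p = 0.0415), which turned to 0.36 with planned normexp. Hoxc6 kept its downward sign with normexp on repaired local backgrounds. The lists were not tested with repaired local backgrounds.

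Without the array labelled WT vehicle replicate 1, Dex in WT cells raised Slc45a3, a member of the sugar transporter family, by 5.38 ± 0.15 (adjusted p = 1.29e-07). Lcn2 rose 36.7-fold (5.20 ± 0.21). Fkbp5 rose 26.4-fold (4.72 ± 0.15, adjusted p = 1.31e-07) and the actin-associated gene Fam107a by 4.74 ± 0.14. The cell cycle regulator gene Rgcc rose by 4.37 ± 0.13, the sulfotransferase gene Sult1a1 by 4.10 ± 0.13 and the clock gene Per1 by 2.14 ± 0.12. Has2, which makes hyaluronan, changed by -3.06 ± 0.15 (adjusted p = 1.87e-06), and Ch25h, a cholesterol hydroxylase, by -2.70 ± 0.086. The chemokine genes Cxcl5, Ccl2 and Cxcl10 changed by -2.17 ± 0.16, -2.09 ± 0.12 and -2.30 ± 0.47 (Cxcl10 was above background on 2 of 3 WT Dex arrays), and Il6 by -1.84 ± 0.14 (adjusted p = 2.65e-05). In all 2548 genes changed, 1120 higher and 1428 lower, of which 603 at least 2-fold (384 higher, 219 lower). The balance turned with normexp on repaired local backgrounds, to 1026 higher and 895 lower. It also turned without the array labelled WT Dex replicate 1 as well, to 2229 higher and 2211 lower, and where a further WT vehicle array was left out, which leaves 1. It was kept without each other WT Dex or GR-C3 array. Of 35 glucocorticoid-induced genes, 28 rose, Angptl4 fell and 6 did not pass (31 rose and 1 fell adjusted over the list alone). Their median was 1.42 (camera adjusted p = 1.28e-36, adjusted p = 9.39e-05 with an estimated correlation). Of 27 inflammatory genes 15 fell and 12 did not pass (16 fell adjusted over the list alone). Their median was -0.62 (camera adjusted p = 1.81e-08, adjusted p = 0.126 with an estimated correlation). Within slide 2, with 1 WT Dex array against 2 WT vehicle arrays, and equally with slide as a block, 1013 genes changed, 595 higher and 418 lower. The lone array is assumed to vary like the other groups, and the array labelled WT vehicle replicate 1, alone on slide 1, does not enter. The glucocorticoid-induced list had a median of 1.5 and the inflammatory list of -0.50.

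In GR-C3 cells, over all 12 arrays, Dex raised Smpd3, a neutral sphingomyelinase, by 1.18 ± 0.10 and Oas1d, of the oligoadenylate synthetase family and above background on 2 of 3 GR-C3 vehicle arrays, by 1.33 ± 0.11 (adjusted p = 0.00219 for both). Igsf21 rose by 1.59 ± 0.19 (adjusted p = 0.0183), Slc35f3 by 1.40 ± 0.20 and the actin-binding gene Ablim1 by 1.19 ± 0.15. Ptx3, a secreted pattern recognition protein, rose by 1.15 ± 0.18 and the adipogenesis gene Medag by 0.98. The cytokine gene Il11 changed by -1.17 ± 0.18 and the olfactory receptor gene Olfr1349, above background on 1 of 3 GR-C3 Dex arrays, by -2.28 ± 0.35 (adjusted p = 0.0471 for both). Spaca5 and Olfr1312 were at least 1.45-fold and at least 1.47-fold lower, as they were not well above background in GR-C3 Dex. Under planned normexp Spaca5 and Olfr1312 turned to 0.24 and 0.29, and with repaired local backgrounds both kept their downward sign. In all 21 genes changed, 16 higher and 5 lower, of which 12 at least 2-fold (7 higher, 5 lower). The spread behind this count was pooled with that of the WT arrays. A fit of the GR-C3 arrays alone called 691 genes, 417 higher and 274 lower. The 21 were chosen in GR-C3 cells, and their median change in the direction of the effect was 1.15 there and 0.22 in WT cells. With quantile normalization 127 changed, 41 higher and 86 lower, and with normexp and quantile normalization 35 rose and 32 fell. The count without each array in turn ran from 2 to 100, apart from 722 without the array labelled WT vehicle replicate 1. The 100 came without the array labelled GR-C3 Dex replicate 1, where the balance turned to 18 higher and 82 lower. It was kept without each other array.

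The glucocorticoid-induced list rose in GR-C3 cells by a median of 0.77 (35 members, camera adjusted p = 2.14e-10, adjusted p = 0.58 with an estimated correlation). Over all genes limma called 0 of its members, and 14 were higher and 1 lower adjusted over the list alone, while 2464 of all genes had an unadjusted p under 0.05. Its member Mt2 changed by 2.56 ± 0.71 (adjusted p = 0.193). The inflammatory list fell by a median of 0.23 (camera adjusted p = 0.000159, adjusted p = 0.58 with an estimated correlation). Of its members Il11 fell and 26 members did not pass (4 fell adjusted over the list alone). Matrix genes rose as a list by a median of 0.12 and genes of sterol synthesis and uptake by 0.15, and Hox genes changed by a median of -0.14. Their camera adjusted p-values were 0.00275, 0.00329 and 0.0238, and for each the adjusted p = 0.58 with an estimated correlation. Planned normexp ended the sterol and Hox calls (adjusted p = 0.0591 and 0.328) and turned the Hox median to 0.12, with camera's sign still downward. Leaving out the array labelled WT vehicle replicate 1 left the GR-C3 changes as they were and lowered the pooled spread. Then 722 genes changed in GR-C3 cells, 436 higher and 286 lower (481 and 556 with quantile normalization). Lcn2 was then at least 42.7-fold higher with Dex, and Sult1a1 rose by 3.64 ± 0.12 and Fam107a by 3.14 ± 0.13. Fkbp5 rose 8.41-fold (3.07 ± 0.14, adjusted p = 4.46e-06) and Mt2 by 2.56 ± 0.12. Ccl2 and Il6 changed by -0.83 ± 0.11 (adjusted p = 0.00312) and -1.17 ± 0.12 (adjusted p = 0.00076). Of the 35 glucocorticoid-induced genes 22 rose, Angptl4 fell and 12 did not pass, and 24 rose and 1 fell adjusted over the list alone. The list was called (camera adjusted p = 1.25e-29, adjusted p = 0.000193 with an estimated correlation). Of the 27 inflammatory genes 7 fell (9 adjusted over the list alone, camera adjusted p = 7.59e-07, adjusted p = 0.226 with an estimated correlation). Within slide 4, with 3 GR-C3 Dex arrays against 1 GR-C3 vehicle array, assumed to vary like the other groups, and equally with slide as a block, 315 genes changed, 189 higher and 126 lower. The medians of the glucocorticoid-induced and inflammatory lists were then 0.83 and -0.35.

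Genes called with limma in both genotypes numbered 1 among the higher, Ackr4 (0.00614 expected for independent lists, n1 × n2 / N), and 0 among the lower (0.00408 expected) with 12 arrays. Leaving out the array labelled WT vehicle replicate 1, 310 genes were higher in both (23.4 expected), 157 lower in both (19.6 expected) and 4 opposite. Of these 4, Kdr, a VEGF receptor, and Abcc9, a subunit of potassium channels, fell in WT and rose in GR-C3 cells (Kdr -0.51 ± 0.12 and 0.59 ± 0.10, Abcc9 -0.42 ± 0.12 and 0.52 ± 0.11). Both were named after their values were seen, and the other 2 go by accessions. The Dex changes of the genotypes correlated across all genes, which are not independent replicates, at a Pearson r of 0.361 and a Spearman rho of 0.372 with 12 arrays. Without that array these were 0.393 and 0.384.

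**Figure D2:**
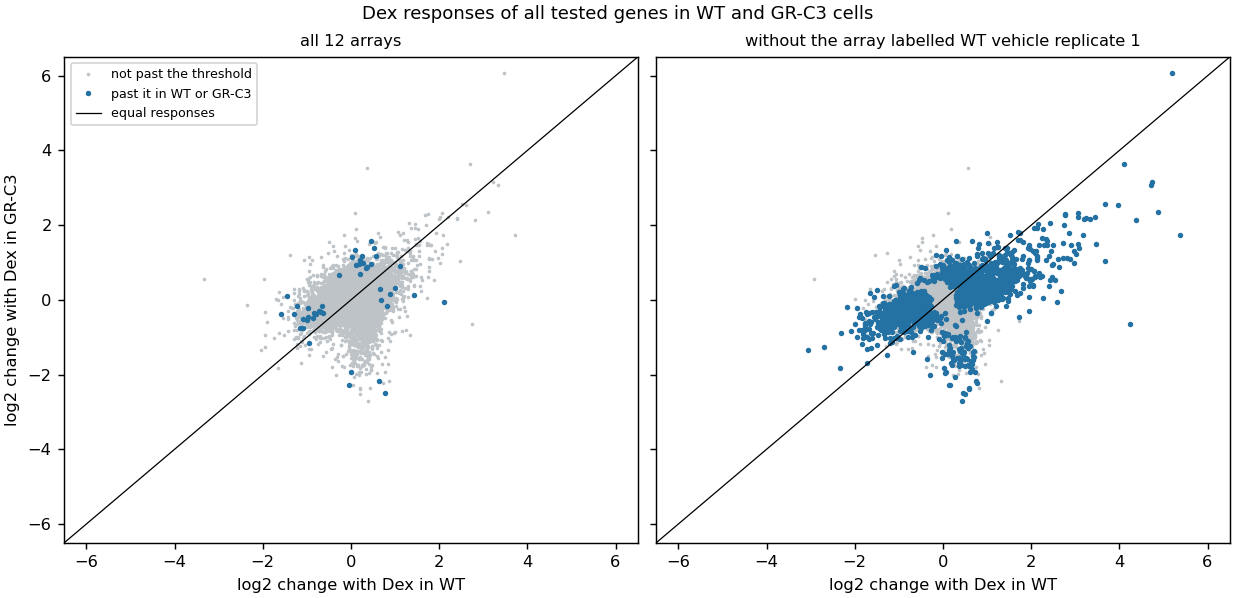
Log2 change with Dex in WT cells (horizontal axis) and in GR-C3 cells (vertical axis) for all tested genes, with all 12 arrays and without the array labelled WT vehicle replicate 1. Genes past the threshold in either genotype are blue, the others are grey, and the line marks equal changes. Without that array Slc45a3 changed by 5.38 in WT and 1.75 in GR-C3 cells.

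Whether the Dex responses of the genotypes differ was tested as an interaction. Over all 12 arrays limma called 0 of 20834 genes, with 1282 at an unadjusted p under 0.05. Other fits called 36 within slides or with slide as a block (lone arms of 1 WT Dex and 1 GR-C3 vehicle array), 1 with a replicate block, 17 without the array labelled GR-C3 Dex replicate 1 and 1021 with array weights. Sterol genes shifted as a list, with a Dex change that lay a median of 0.31 higher in GR-C3 than in WT cells (camera adjusted p = 0.000132, adjusted p = 0.855 with an estimated correlation). Of its 20 members 0 were called over all genes and 3 were higher adjusted over the list alone. The size of the response was compared over 447 genes with an average Dex effect (210 higher, 237 lower). Their median change in the direction of the effect was 0.59 in WT and 0.52 in GR-C3 cells, a ratio of 0.87. The camera test of the difference gave a p of 0.233. The ratio was 1.24 for the higher genes and 0.769 for the lower. The median difference was -0.09, and turned to 0.14 without the array labelled WT vehicle replicate 3, so the 12 arrays set no direction for it.

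With 11 arrays, leaving out the array labelled WT vehicle replicate 1, 237 genes had an interaction, 67 with a more positive and 170 with a more negative Dex change in GR-C3 cells. The increase seen in WT cells was smaller or not past the test in GR-C3 cells for Slc45a3 (interaction -3.64 ± 0.20, adjusted p = 6.65e-05), Tcim (-2.62 ± 0.15) and Ramp2, a co-receptor of the adrenomedullin receptor (-2.43 ± 0.13). Tcim changed by 2.58 ± 0.11 in WT and by -0.05 ± 0.098 in GR-C3 cells. The increase was also smaller for Fkbp5 (-1.65 ± 0.21, adjusted p = 0.00648), the kinase gene Sgk1 (-1.29 ± 0.14), Errfi1, an inhibitor of EGFR (-1.76 ± 0.13), and the transcription factor gene Cebpd (-1.60 ± 0.16). Starting levels under vehicle lay 1.17 higher in GR-C3 than in WT cells for Errfi1 and 0.40 higher for Fkbp5, and differed by -0.20 for Cebpd. The decrease was smaller for Has2 (1.72 ± 0.20, adjusted p = 0.00411), Ch25h (1.43 ± 0.12), Cxcl5 (1.97 ± 0.22, with a GR-C3 change of -0.20 that did not pass), Ccl2 (1.26 ± 0.16, adjusted p = 0.00734) and Irf1 (0.80 ± 0.12). Per1 (-0.22, adjusted p = 0.569), Tsc22d3 (-0.49, 0.332) and Il6 (0.67, 0.132) did not pass. The glucocorticoid-induced gene Lcn2 went the other way, with a fitted interaction of 0.88 that rests on GR-C3 vehicle signals near background. Of the 35 glucocorticoid-induced genes 11 had a more negative change in GR-C3 cells and 24 did not pass (20 lower and 1 higher adjusted over the list alone). Their median was -0.67 (camera adjusted p = 2.57e-18, adjusted p = 0.000964 with an estimated correlation), and within slides it was -0.64. Over 2967 genes with a called average Dex effect, in which WT had a weight of 0.444, the median change was 0.58 in WT and 0.33 in GR-C3 cells, a ratio of 0.561, and 81.4% of them changed less in GR-C3 cells (a camera p of 3.67e-18 at the preset correlation). An estimated correlation, with which most list calls of this comparison were lost, was not tried for this p. Within slides the ratio was 0.664 over 1513 genes (a camera p of 5.82e-17). This rests on 1 WT Dex array and 1 GR-C3 vehicle array as lone arms and again leaves out the array labelled WT vehicle replicate 1. With slide as a random block on all 12 arrays the median difference was -0.13 (a camera p of 0.0921).

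Under vehicle, GR-C3 cells held far more Hoxd13, a posterior and limb patterning gene (chromosome 2, 74514907 to 74514966, build mm7), than WT cells. Its level was 0.74 ± 0.082 against -5.08 ± 0.31 (SD, n = 3), a difference of 5.82 ± 0.22 (adjusted p = 8.82e-08). Ppbp, a platelet chemokine gene, lay 5.15 ± 0.22 higher and the cadherin gene Cdh16 4.04 ± 0.21. The connexin gene Gjb2 lay 4.27 ± 0.45 higher and the muscle light chain gene Myl1, above background on 2 of 3 WT vehicle arrays, 3.68 ± 0.20. Arg1, which breaks down arginine, was at least 9.02-fold higher. Gdf10, a BMP family ligand, lay at -2.42 ± 0.10 in GR-C3 and 3.20 ± 0.11 in WT cells, a difference of -5.62 ± 0.096 (adjusted p = 1.3e-10). Cytl1, made by cartilage cells, differed by -6.23 ± 0.33, and Cnmd, the cartilage protein chondromodulin, was at least 109-fold lower in GR-C3 cells. In all 5161 of 20834 genes differed, 3037 higher and 2124 lower in GR-C3 cells, of which 1185 at least 2-fold (573 higher, 612 lower). The median difference of all genes was 0.11, and 0.06 with quantile normalization, which called 2686 higher and 2463 lower. Without the array labelled WT vehicle replicate 1, 5689 differed. The balance turned with slide as a block, to 753 higher and 876 lower of 1629, and with planned normexp, to 158 and 220 of 378 around a median of all genes of 0.29. Without the array labelled GR-C3 vehicle replicate 2 there were 3242, and no slide held both genotypes under the same treatment.

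The arrays also differed in sex-linked genes along with the genotype. The Y-linked genes Ddx3y and Eif2s3y were at least 287-fold and at least 299-fold lower in GR-C3 vehicle than in WT vehicle, Uty at least 9.15-fold lower, and Kdm5d differed by -3.76 ± 0.24 (adjusted p = 2.14e-06). Xist, the RNA of the silenced X chromosome, was higher in GR-C3 cells by 1.499 ± 0.16 (adjusted p = 6.24e-05). The probe used was well above background on 6 of 6 WT arrays too. Its 3 other probes were well above background on 6 of 6 GR-C3 and 0 of 6 WT arrays. They had fitted differences under vehicle of 10.1, 6.38 and 7.89, which rest on WT signals near background. These sex-linked differences moved with every gene group given for the genotype.

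Of 32 measured Hox genes, which record body position in fibroblasts, 26 were higher in GR-C3 vehicle, 2 lower and 4 did not pass, with 26 and 2 also adjusted over the list alone. The list was called (median 1.66, camera adjusted p = 2.08e-17, adjusted p = 0.00327 with an estimated correlation). Hoxc9 was higher by 2.32 ± 0.11, Hoxa10 by 2.06 ± 0.097 and Hoxb7 by 2.01 ± 0.11. Of 15 chondrocyte markers 14 were lower, also adjusted over the list alone, and 1 did not pass (median -1.32, camera adjusted p = 1.58e-15, adjusted p = 0.096 with an estimated correlation). Among them were the cartilage collagen genes Col2a1 at -3.21 ± 0.10, Col9a3 at -4.18 ± 0.15 and Col9a1 at -2.01 ± 0.17. Of 9 osteoblast markers 1 was higher, 4 were lower and 4 did not pass (2 and 4 adjusted over the list alone). Among the lower were Dmp1 at -3.08 ± 0.25, above background on 2 of 3 GR-C3 vehicle arrays, and Bglap at -1.64. The osteoblast list was called lower (camera adjusted p = 0.0495, adjusted p = 0.353 with an estimated correlation) with a mean of -0.62 but a median of 0.00302. It was not called with slide as a block (adjusted p = 0.411), with quantile normalization (median -0.03, 0.0557) or without the array labelled WT vehicle replicate 1 (0.0551). Of 22 skeletal muscle markers 9 were higher and 13 did not pass (9 adjusted over the list alone, camera adjusted p = 0.00223, adjusted p = 0.353 with an estimated correlation). The embryonic myosin gene Myh3 was higher by 2.98 ± 0.25 and was above background on 2 of 3 WT vehicle arrays. Of 12 neural markers 6 were higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.0195, adjusted p = 0.353 with an estimated correlation). The radial glia gene Fabp7 differed by 1.97 ± 0.16 and Gap43, of growing axons, by -1.49. With slide as a block the Hox and chondrocyte medians were 1.55 and -1.11, and that of skeletal muscle genes fell from 0.44 to 0.17.

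**Figure D3:**
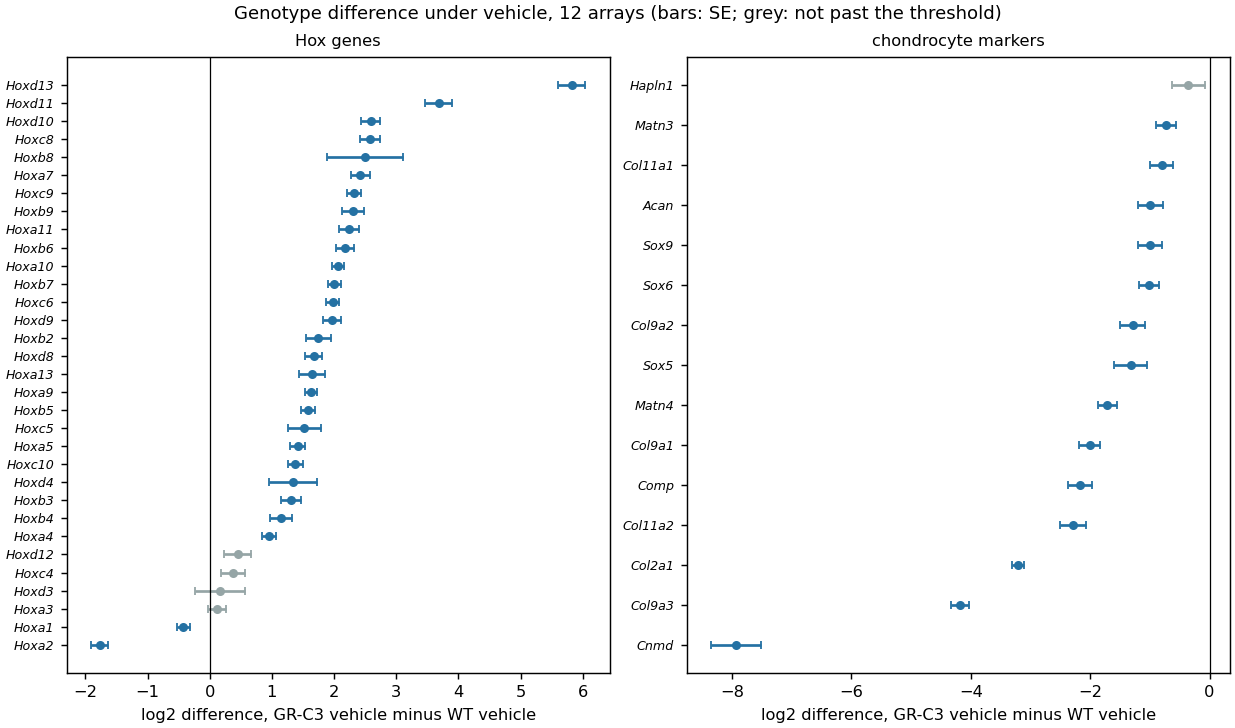
Log2 difference of GR-C3 vehicle minus WT vehicle (axis of values) for each measured Hox gene and chondrocyte marker, with bars for the SE and grey for genes that did not pass the test (n = 3 arrays per group). Of the Hox genes 26 of 32 were higher in GR-C3 cells, and of the chondrocyte markers 14 of 15 were lower.

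Of 26 mitotic genes 17 were higher in GR-C3 vehicle and 9 did not pass (18 higher and 1 lower adjusted over the list alone). The list was called (median 0.47, camera adjusted p = 3.14e-05, adjusted p = 0.264 with an estimated correlation), and among the higher were the centromere gene Cenpa at 0.94 ± 0.12 and the mitotic kinase gene Plk1 at 0.88 ± 0.13. Of 22 replication genes 8 were higher (8 adjusted over the list alone, camera adjusted p = 0.0195, adjusted p = 0.627 with an estimated correlation). This list call was lost without the array labelled WT vehicle replicate 1 (adjusted p = 0.158) and with slide as a block. Serum-responsive immediate early genes were higher in 12 and lower in 1 of 22 (13 and 1 adjusted over the list alone), with Egr2 at 1.56 ± 0.17 and Jun at 1.04. The list was called (camera adjusted p = 0.047, adjusted p = 0.353 with an estimated correlation), but not with quantile normalization (adjusted p = 0.0774). Planned normexp ended the list calls of immediate early (adjusted p = 0.116), replication (0.0908), neural (0.112) and skeletal muscle genes (0.0518). Inflammatory genes were higher in 13 and lower in 2 of 27 (16 and 2 adjusted over the list alone, camera adjusted p = 0.00429, adjusted p = 0.438 with an estimated correlation). The protease genes Mmp9 and Mmp3 differed by 1.90 ± 0.16 and -1.91 ± 0.12. Interferon-stimulated genes were higher in 1 and lower in 11 of 27 (1 and 11 adjusted over the list alone, camera adjusted p = 0.00174, adjusted p = 0.353 with an estimated correlation). Their median of -0.27 was -0.53 with slide as a block and -0.05 with planned normexp. The antiviral tethering factor gene Bst2 differed by -1.22 ± 0.13. Of the 35 glucocorticoid-induced genes 9 were lower and 1 higher (11 and 1 adjusted over the list alone, median -0.60, camera adjusted p = 0.000245, adjusted p = 0.661 with an estimated correlation). Klf15 differed by -2.40 ± 0.58 (-1.47 without the array labelled WT vehicle replicate 1) and Angptl4 by 1.58 ± 0.13. The median without the array labelled WT vehicle replicate 1 was -0.01, with 6 higher and 11 lower (camera adjusted p = 0.0746), and with slide as a block it was -0.10 (adjusted p = 0.186).

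Under Dex, Hoxd13 was higher in GR-C3 than in WT cells by 5.68 ± 0.22 (adjusted p = 1.17e-07) and Ppbp by 5.04 ± 0.22, and Cnmd was at least 138-fold lower. Ddx3y was at least 215-fold lower, and Eif2s3y differed by -9.07 ± 0.52 with 1 of 3 GR-C3 Dex arrays above background. By the probe that was also well above background on the WT arrays, Xist was higher by 1.62 (adjusted p = 3.37e-05). In all 6174 genes differed, 3654 higher and 2520 lower, of which 1488 at least 2-fold (661 higher, 827 lower). The median difference of all genes was 0.13, and 0.05 with quantile normalization, which called 3072 higher and 3167 lower. Of the Hox genes 26 were higher and 1 lower of 32 (26 and 2 adjusted over the list alone, and 26 and 2 with 11 arrays), and of the chondrocyte markers 12 were lower of 15 (14 adjusted over the list alone). Of 20 sterol genes 13 were higher (15 adjusted over the list alone). Of 27 inflammatory genes 19 were higher and 2 lower (21 and 2 adjusted over the list alone), with Cxcl5 at 3.72. Of the 35 glucocorticoid-induced genes 1 was higher and 10 lower (1 and 10 adjusted over the list alone), among the latter Rgs2, a regulator of G protein signalling, at -2.51 and the phosphatase gene Dusp1 at -1.07. With 11 arrays, leaving out the array labelled WT vehicle replicate 1, 1 was higher and 25 were lower (1 and 26 adjusted over the list alone). With 11 arrays 8484 differed. With slide as a block 3221 genes differed, 1586 higher and 1635 lower, with planned normexp 456 around a median of all genes of -0.40, and without the arrays labelled WT Dex replicate 3 and GR-C3 Dex replicate 3 in turn 4110 and 4001.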

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

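Leaving out each array in turn was planned for counts, response size and named genes. Chosen after the results were seen were the list tests without the array labelled WT vehicle replicate 1, the genes named from that fit, the use of 11 arrays in the test of starting levels, the tests of that array's profile, and the count and ratio within slides.

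The Dex responses of GR-C3 and WT cells differed by a test of the difference itself in the following results. Over all 12 arrays the sterol list differed (camera adjusted p = 0.000132, adjusted p = 0.855 with an estimated correlation). Without the array labelled WT vehicle replicate 1, 237 genes differed. So did the lists of glucocorticoid-induced (camera adjusted p = 2.57e-18, adjusted p = 0.000964 with an estimated correlation), inflammatory (0.00109), adipocyte (0.000165), sterol (9.84e-05), hypoxia (0.00668), heat shock (0.0158) and replication genes (0.0158). Of these list calls, the glucocorticoid-induced one was kept with an estimated correlation, and the others then had an adjusted p of 0.349 to 0.55. The size of the Dex response differed with a camera p of 3.67e-18 at the preset correlation, and an estimated correlation was not tried for it.

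Single genes whose Dex change differed without that array, as GR-C3 minus WT on the log2 scale, were Cxcl5 (1.97), Pdzrn4 (1.77), Rassf9 (1.73), Has2 (1.72), Ch25h (1.43), Pdgfb (1.43), Fgf5 (1.35) and Tgtp1 (1.31). In the other direction they were Nat3 (-4.88), Slc45a3 (-3.64), Spaca5 (-2.97), Xlr5d (-2.96), Kcna5 (-2.64), Tcim (-2.62), Klk1b16 (-2.50) and Ramp2 (-2.43). Nat3, Spaca5, Xlr5d and Klk1b16 had a group with 0 arrays above background, so their fitted differences are not measured sizes. Kcna5 was above background on 1 of 3 WT vehicle arrays and Fgf5 on 2 of 3 WT Dex arrays.

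The array labelled WT vehicle replicate 1 lay with the Dex arrays in the genes that Dex changes. On a scale from 0 for the other WT vehicle arrays to 1 for the WT Dex arrays, over 691 genes (417 higher, 274 lower) chosen from the GR-C3 arrays alone, it lay at 0.983, while GR-C3 vehicle arrays lay at -0.24 to -0.208 and GR-C3 Dex arrays at 0.615 to 0.672. A slide or scan-day effect alone would not move the genes that Dex changes in other arrays this far, but this array alone held slide 1 and scan day 2, which cannot be told apart from it and stay open for its remaining distance from the WT Dex arrays (correlations of 0.988 to 0.989 against 0.992 to 0.995 among these). A swap with a WT Dex array would need 1 of these to lie near 0, while the lowest lay at 0.96. RNA of WT cells exposed to a glucocorticoid under a vehicle label may be the source, with the same position of 0.983 and a median of the Y-linked genes of -0.277, just below the other WT arrays (-0.199 to 0.102) and far above the GR-C3 arrays (-8.93 to -6.26).

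Dex responses were smaller in GR-C3 than in WT cells without that array. A slide effect stays open, although the ratio of 0.664 within slides 2 and 4 lay under the bound set beforehand for excluding it (0.596 to 0.739 when other arrays than the lone ones were left out). That bound did not allow for the design, in which each response within a slide rests on a lone array, WT Dex replicate 1 or GR-C3 vehicle replicate 3, that could not be left out. Differences of 0.25 or more in the starting level under vehicle were unlikely as the whole cause. The ratio was 0.561 over 1118 genes whose vehicle means differed by under 0.25, with a range of 0.466 to 0.745 when arrays were left out. The highest of these lay only just under the bound set beforehand for excluding this cause. The vehicle means were not taken anew when arrays were left out. Smaller differences in starting level stay open, since 0.25 is close to the median difference in response (-0.2649). A smaller response through the GR-C3 isoform stays open as a hypothesis, as does any difference between the cultures that goes with genotype, such as sex, which was not tested here.

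Other splits of the samples were counted for each comparison. For Dex in WT cells 2 of 10 splits gave at least the real 25 genes, and the highest other gave 2136. That split set the array labelled WT vehicle replicate 1 with WT Dex replicates 2 and 3 against the rest and points to a structure of the samples. Slide was shared by WT vehicle replicates 2 and 3 and WT Dex replicate 1, the 3 arrays on the other side of that split, and the count within slides, with that WT Dex array as a lone arm, was 1013. For Dex in GR-C3 cells 1 of 10 splits, the real one, gave 21 genes and the highest other 0. For genotype 1 of 10 splits gave 5161 under vehicle and 6174 under Dex, with 0 as the highest other in both. In these 4 comparisons 10 splits are too few for a share under 0.05. For the interaction the real count was 0, which all 100 splits drawn must reach, so their number decides nothing. The highest other gave 9048. That split kept the vehicle groups and regrouped the Dex arrays across genotypes, so the genotype difference itself enters its count. For the average Dex effect 1 of 100 splits drawn, the real one, gave 447 genes, with 269 as the highest other. This share lies under 0.05. The splits take the arrays as exchangeable, while slide partly went with treatment, so they do not exclude a slide effect.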

How the results depend on the processing

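Some settings were chosen after seeing the data: values without the array labelled WT vehicle replicate 1 combined with another setting or for lists, normexp with repaired local backgrounds, and counts and response size within slides. Counts of genes are given as Dex in WT, Dex in GR-C3, interaction, genotype under vehicle and genotype under Dex (25, 21, 0, 5161 and 6174), and counts that are left out were within 1.5 times.

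Planned normexp gave 0, 0, 378 and 456 (Dex in each genotype, genotype under each treatment) and no genes for the size of the response. Local backgrounds with an outlier call reached 65361 there, against at most 73 elsewhere. With these replaced, 38 genes changed with Dex in WT. Normexp with quantile normalization gave 126 and 67 for Dex, quantile normalization 127 for Dex in GR-C3, no filter 0 and 10, and the mean of a gene's probes 15 and 12. Slide as a block gave 1013, 315, 36, 1629 and 3221, the same for Dex within slides, and a random slide 84 and 35. The trend and robust options gave 60 and 42, array weights 4233, 5048, 1021 and 10252 (the array labelled WT vehicle replicate 1 had the lowest weight, 0.105), and fits of only the groups compared 0 and 691. A threshold of 0.01 gave 0, 2, 2669 and 3114, and a 2-fold demand 10, 12, 1185 and 1488, by construction. The replicate block gave 0, 10 and 1 for Dex and the interaction, with same-numbered samples correlating at -0.215 to 0.179, so the numbers do not pair samples. Behind the counts of 0 for Dex in WT, limma had 2054 to 12210 genes at an unadjusted p under 0.05, and 197 for Dex in GR-C3 with planned normexp. Without each array in turn the counts ran 0 to 2548, 2 to 722, 0 to 237, 3242 to 5689 and 4001 to 8484. Without the array labelled WT vehicle replicate 1 and each other array they ran 961 to 4440, 305 to 1152, 58 to 1184, 2551 to 6885 and 6318 to 9325. Without that array, quantile normalization gave 2927, 1037 and 362 and repaired normexp 1921, 389 and 224.

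The median difference in response size (-0.08939) was -0.07469 with normexp and quantile normalization, -0.2656 by slide, -0.1069 with trend and robust options, -0.1906 with array weights, -0.4988 over genes called in WT alone and 0.8434 over those called in GR-C3 alone, the last pair by construction. Without single arrays it ran from -0.2649 to 0.1448. Lists called (10, 5, 1 and 11) were 0, 0, 0 and 1 with an estimated correlation, 0, 0, 0 and 21 with fry, 18 with planned normexp for both WT and interaction, 12 and 6 by slide for GR-C3 and interaction, and 10 and 7 without the array labelled WT vehicle replicate 1.

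Planned normexp turned camera's sign for some lists called in either setting, whose medians there follow. For Dex in WT they were matrix -0.281, contractile -0.419, interferon 0.52, TGF-beta and BMP -0.336, hypoxia -0.0457, p53 -0.407, heat shock -0.285, insulin-like growth factor -0.354, Hox 1.44 and macrophage 1.37. The median of all genes was 0.551 there, and the inflammatory median turned to 0.644 with camera's sign still downward. For the interaction, around a median of all genes of -0.458, they were matrix 0.335, protease 0.257, contractile 0.383, immediate early 0.35, TGF-beta and BMP 0.241, hypoxia 0.198, p53 0.366, heat shock 0.352, receptor pathway 0.171, Hox -1.36 and hepatic -1.69. Fry called the pericyte list by genotype upward (median 0.12) and camera gave it a downward sign. Genes that turned under planned normexp were Tdrd9 2.217, Ccl4 2.161, Spata5l1 2.316, Pde4b 0.4071, Prtg 1.443, Cdc14a 0.9567 and Hoxc6 0.3645 (Dex in WT), Spaca5 0.238 and Olfr1312 0.2879 (Dex in GR-C3), Mrc1 0.5127 and Ptprc 0.02907 (genotype, vehicle) and ccdc198 -0.1805 (genotype, Dex). With repaired normexp Tdrd9 and Spata5l1 stayed turned (0.08963 and 0.1242), and the others of these genes kept the sign of the main setting. Eda2r by genotype turned with the mean of probes (-0.09502). The Mt2 interaction (0.03292) also turned and ran from -1.126 to 0.6181 without single arrays, the lowest without the array labelled WT vehicle replicate 1. Except where stated, the cause was not tested. Of 15386 alternative values of named genes 14042 kept their side of the threshold without a called value turning, 597 became weaker, 731 stronger and 16 reversed, and of 1190 for lists 1012, 67, 89 and 22. Among the 14042 and 1012, 607 and 106 that were not called in either setting changed sign. Changes of genes near background rest on few arrays above it.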

Other observations

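The test of body regions was chosen after the results were seen.

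Single members of other gene groups differed between GR-C3 vehicle and WT vehicle. Of 50 measured patterning factors of limb, body wall and head, 18 were higher, 11 lower and 21 did not pass (18 and 13 adjusted over the list alone). The head and face factor gene Alx1 was higher by 2.47 ± 0.13 (SE) and Lhx9, of limb and gonad, by 2.55 ± 0.14, while Barx1 differed by -2.20 ± 0.099 and Foxd1 by -2.20 ± 0.12. Of 26 Wnt genes 7 were higher and 13 lower (7 and 13 adjusted over the list alone), with Wnt4 at 2.08, Dkk2 at 2.01, the secreted inhibitor gene Sfrp1 at -2.19 and the receptor gene Fzd1 at -1.87. Of 13 genes of the insulin-like growth factor axis 2 were higher and 6 lower (2 and 7 adjusted over the list alone), with the growth factor gene Igf2 at 2.31 ± 0.12, the binding protein gene Igfbp5 at 2.40 ± 0.095 and Igfbp4 at -2.17. Camera did not call these 3 lists (adjusted p of 0.887, 0.104 and 0.104).

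Single markers of some other cell types also differed by genotype, and camera called none of these lists. Of all genes tested, 5161 of 20834 differed. Of 9 Schwann cell, neural crest and melanocyte markers 4 were higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.104), with the glial genes Erbb3 at 2.19 and Sox10 at 1.67. Of 9 epithelial markers 3 were higher and 1 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.316), with the keratin genes Krt19 at 2.77 and Krt18 at 2.30. Of 9 endothelial markers 2 were higher (2 adjusted over the list alone, camera adjusted p = 0.143), Emcn at 1.89 and the VEGF receptor gene Kdr at 1.44. Of 15 macrophage and leukocyte markers 1 was higher and 4 lower (2 and 5 adjusted over the list alone, camera adjusted p = 0.138), with the pan-leukocyte gene Ptprc at -1.25 and the mannose receptor gene Mrc1 at -1.08, which turned to 0.029 and 0.51 with the planned normexp correction. Ptprc and Mrc1 kept their downward sign with normexp on repaired local backgrounds. None of 8 erythroid markers passed with limma, over all genes or adjusted over the list alone, and camera did not call the list (adjusted p = 0.539).

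WT and GR-C3 arrays differed in 5161 genes under vehicle. Kept probes of the Y-linked genes Ddx3y and Uty were well above background on 6 of 6 WT and 0 of 6 GR-C3 arrays. For the Xist probes other than the one used it was the reverse, the pattern of male WT and female GR-C3 cells. Sex-linked genes were thus part of the difference, and how much of the rest went with sex stays open. X-linked genes that escape silencing had a median difference of 0.596. Kdm5c lay at 0.73, Eif2s3x at 0.81, Ddx3x at 0.46 and Kdm6a at -0.06, of which the last did not pass. Of 1178 genes with a 2-fold change 5.77% lay on X or Y (3.52% of all genes tested), so genes of these chromosomes were a small part of the difference. This share cannot exclude sex as the whole cause, since X and Y hold few of the genes tested and sex went with genotype on every array. Cultures that hold cells of different body regions are a further hypothesis, as the Hox list was called even with an estimated correlation (adjusted p = 0.00327). Donor DNA around the edited gene could not be decided: within 10 Mb of Nr3c1 55 of 182 genes (30.2%) were called against 24.7% of 20478 elsewhere, a ratio of 1.22 (Fisher's exact test, p = 0.101), and the effect of the GR-C3 isoform itself stays open and cannot be told apart from it by these arrays.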
